A study of Mus musculus with 18 samples.

How the data were processed

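RNA from the ventricular myocardium of 18 mice was measured on Affymetrix oligonucleotide arrays, 1 array per sample. Per the labels' protocols, total RNA was prepared from heart tissue and converted to biotin-labelled cRNA, and the mice were killed in the early morning. The deposited table holds 1 linear signal intensity per probe set and array, which the authors computed with MAS5, per the submitters' processing notes. MAS5 is the Affymetrix method that combines the perfect-match and mismatch probes of a set into a single signal. Its version and settings are not given in the sources used here, and the table holds no detection calls. Checked on the table, the mean after leaving out the lowest and highest 2% of probe sets was 100.001 on every array, so the deposited intensities carry a scaling of each array to a common trimmed mean. Such a scaling removes differences in total signal between arrays, and a change in total RNA per cell cannot be read from these values.

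The samples were grouped by their labels into wild type C57Bl/6J mice (n = 4), ob/ob mice fed ad libitum (n = 4), ob/ob mice on calorie restriction (n = 5) and ob/ob mice given leptin by osmotic mini-pump (n = 5). The ob/ob mice were 6 months old and treatment lasted 1 month. The stated age of the wild type mice begins at 6 months and runs somewhat higher than that of the ob/ob mice, so genotype and age were not fully separated. All p-values measure the spread between these samples.

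Of the 45101 probe sets, 64 were control sets and were left out of the tests. The platform annotation paired 34945 sets with 1 gene symbol and 932 with several, and 9160 were not listed. Only sets with 1 symbol were used. Entrez identifiers of 34754 sets were found in a RefSeq gene table (assembly GRCm38.p6, used for names and for which genes neighbour each other), and 0 symbols changed through it. Each gene was represented by its probe set with the highest mean, giving 18193 genes. Signals were transformed as log2(signal + 5.13), where 5.13 is the 20th percentile of all signals. Genes whose mean lay under the 40th percentile (4.36 on this scale) were left out, and 13359 genes were tested. Log2 changes are on this scale, which understates the change of genes with low signal. For arrays, the number of samples per group limits the precision.

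Differences were tested in R 4.3.3 with limma 3.58.1. One model with a coefficient per group was fitted over all 18 arrays, so that the groups shared 1 estimate of the spread, and 6 contrasts were taken with empirical Bayes moderation. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, with no fold threshold. All adjusted p-values given for single genes come from this limma fit. Errors of log2 changes are standard errors of the fit, and errors of signals are SDs between arrays. The number of genes expected at an unadjusted p under 0.05 with no difference was 668.

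Of 50 gene lists fixed for heart tissue, 46 held at least 5 tested genes. They cover pathways of fuel use, stress and signalling and markers of the cell types a ventricular sample can hold. Each was tested with limma's camera, which compares a list's genes with all other genes, at the preset inter-gene correlation of 0.01. Adjustment was over the 46 lists. The same test with the correlation estimated from the arrays, and limma's fry, which asks whether a list's genes move on balance to 1 side without comparing them with other genes, were run beside it. With the estimated correlation, 2 list calls over the 6 comparisons held: interferon responsive genes in leptin against calorie restriction and in calorie restriction against wild type. For members of a list the number called was also computed adjusted over the list alone.

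The genes named in the text followed a rule. It took the 8 called genes with the largest log2 change in each direction of a contrast (4 for the treated groups against wild type). Where fewer than 4 were called in a direction, it took the 4 with the smallest p, named as not called. It also took up to 4 members with the smallest p of each described list, and a fixed set of genes of fuel use and cardiac load. Unnamed cDNA clones were to be passed over, and 0 were met. Of the fixed set, Cpt1b and Ucp2 were not analysed here. Groups, contrasts, tests, gene lists, the naming rule and most alternatives were chosen before the data were examined.

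Comparisons that share the ad libitum or wild type arrays have correlated errors. For these, 100 draws of simulated unchanged groups, with no difference between any of the groups, gave the value that shared arrays produce alone. The ad libitum arrays were also split so that different arrays entered the 2 comparisons. The complete procedure was tested on simulated data with 13359 genes and known changes in 100 genes per fold size. For ad libitum against wild type it recovered 44% of genes changed 1.5-fold and 76% of those changed 2-fold, with 4% of calls false. For leptin against ad libitum these values were 48%, 76% and 8.15%, and for leptin against calorie restriction 49%, 80% and 5.15%. In each of these simulations 0 unchanged lists were called by camera. The genes were simulated as independent of each other, so this count does not test camera on lists whose genes vary together.

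Alternatives were the pseudocount, the filter, quantile normalization, median centring, array weights, a trended and robust prior, every probe set in place of 1 per gene, fits of only the 2 groups compared, the replicate number as a block, and each array left out in turn. After the data were seen, fits without calorie restricted replicates 2 and 3, and with the atrial marker signal as a covariate, were added, because those 2 arrays carried high signals of atrial genes. Quality measures of the arrays were compared between groups by exact permutation tests.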

Results

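Transcript levels in the ventricular myocardium were measured on 18 arrays. The arrays came from lean wild type mice (n = 4), from leptin-deficient ob/ob mice that ate ad libitum (n = 4), from ob/ob mice whose food was restricted to the intake of the leptin treated animals (n = 5) and from ob/ob mice that received leptin (n = 5). The ob/ob mouse lacks functional leptin, the fat-derived hormone that lowers food intake, and becomes obese. The 2 treated groups were matched in food intake and differed in leptin. The title of the series concerns fat storage in the heart muscle under calorie restriction, so genes of fatty acid handling were among the lists fixed for the comparisons.

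The arrays had similar signal. The median signal per array lay between 22.3 and 31.8 and the 75th percentile between 92.7 and 101. Between 16.7% and 22.7% of probe sets were at or below the pseudocount. The ratio of 3' to 5' signal, a measure of RNA integrity, was 0.797 to 0.868 for Gapdh and 1.13 to 1.41 for actin. Log2 signals of any 2 arrays correlated at 0.943 to 0.971 across probe sets, and no 2 arrays were identical. The first 2 principal components held 18.9% and 13.2% of the variance. Of 36 differences in quality measures between groups, the lowest adjusted p was 0.893 by exact permutation tests, which could not have passed a single difference with so few arrays per group.

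Lep itself was close to background in every group, with mean signals of 4.11 to 8.06 (n = 4 or 5), so the array could not check the genotype at the mutated gene. Lepr, the leptin receptor, had mean signals of 24.9 ± 14.4 in wild type, 30.9 ± 8.67 in ad libitum, 31.9 ± 9.19 in calorie restricted and 29.9 ± 10.8 in leptin treated hearts (SD), and it was not called in any comparison. Atrial transcripts were uneven in the calorie restricted group. Myl7, the atrial myosin light chain, had signals of 3448 and 3548 in calorie restricted replicates 2 and 3, while the other 3 arrays of the group lay between 3.58 and 635. Myl4 had signals of 3213 and 3573 in these 2 arrays, and Sln, which encodes the atrial calcium pump regulator sarcolipin, had 1918 and 2038.

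**Figure D1:**
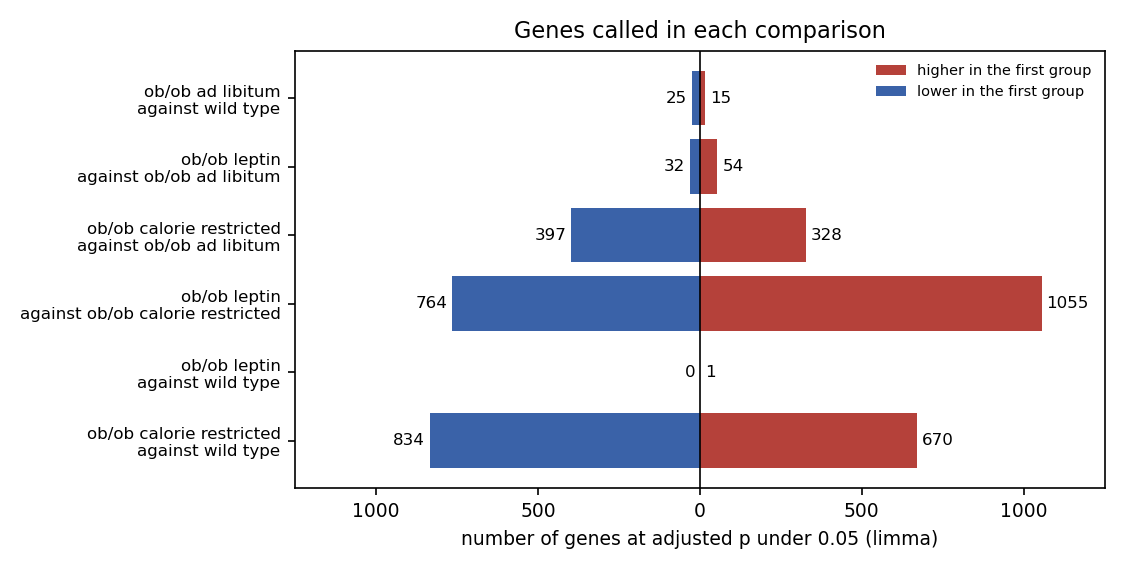
Number of genes called higher (bars above 0) and lower (bars below 0) in each of the 6 comparisons, of 13359 genes tested at an adjusted p under 0.05. The comparisons that involve the calorie restricted group hold 725, 1819 and 1504 genes, and those without it hold 40, 86 and 1.

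Untreated ob/ob hearts were first compared with wild type hearts, which asks what leptin deficiency and obesity do to the ventricle. Ppargc1a, the coactivator that drives mitochondrial gene expression, fell from a signal of 1288 ± 192 in wild type to 567 ± 28.6 in ad libitum hearts (SD, n = 4 each), a log2 change of -1.17 ± 0.11 (SE, adjusted p = 1.04e-04). Kcnk1, a potassium channel subunit, rose from 49.8 ± 9.37 to 208 ± 33.2 (1.96 ± 0.14, adjusted p = 1.08e-06). G0s2, an inhibitor of the triacylglycerol lipase encoded by Pnpla2, fell by 0.85 (adjusted p = 0.0164). In total, 40 genes passed the test, 15 higher and 25 lower in ad libitum hearts.

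Other genes that rose were Asf1b (1.43), a histone chaperone, Cdo1 (1.26), which oxidises cysteine towards taurine, and Egln3 (1.07), an oxygen-dependent hydroxylase of hypoxia-inducible factor. Cacng6 (1.05), a calcium channel subunit, Col5a3 (0.96), a collagen chain, Gsta4 (0.90), a glutathione transferase for lipid aldehydes, and Cyp2d22 (0.87), a cytochrome P450, rose as well. Genes that fell included Aldh1a2 (-2.09 ± 0.37), which makes retinoic acid, Clec1b (-1.95), a receptor best known from platelets, Nr4a3 (-1.74), an orphan nuclear receptor, and Ifitm1 (-1.06), an interferon-induced membrane protein. Ms4a6d (-1.06), Klf10 (-1.05), a transcription factor induced by TGF-beta, and Tmem100 (-0.99), an endothelial membrane protein, completed the 8 with the largest falls. Kcnk1, Ppargc1a, Col5a3 and Tmem100 stayed called whichever single array of the 2 groups was left out. The other 12 of these 16 genes, G0s2 and the clock gene Nr1d2 did not. The signal of Clec1b in ad libitum hearts (mean 3.98) lay under the pseudocount of 5.13, so the size of its change here and in the later comparisons depends on the pseudocount. Atrial signal was uneven between arrays here too, with Myl7 at 2.52 to 4.73 in 3 of the 4 ad libitum arrays, 438 in replicate 1 and 92.7 to 674 in wild type, though 0 of the 10 atrial markers had an unadjusted p under 0.05. With the atrial marker signal as a covariate 10 genes were called, and 9 of the 18 named genes lost their call: Cdo1, Clec1b, Egln3, Gsta4, Ifitm1, Klf10, Ms4a6d, Nr1d2 and Nr4a3. The number of genes called was 11, 19, 5 and 12 without ad libitum replicate 1, 2, 3 or 4, and 15, 5 and 13 without wild type replicate 1, 2 or 4.

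Camera with the preset correlation placed several lists of energy production slightly above other genes in ad libitum hearts, but this was lost with an estimated correlation and a rise was not shown. Of 76 genes of oxidative phosphorylation, 73 had a positive log2 change with a median of 0.14, such as Sdhd (0.29) and Uqcr10 (0.22), but 0 were called by limma, 3 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. Camera placed the list above the other genes (adjusted p = 6.67e-09), and the adjusted p was 0.695 with an estimated correlation. After quantile normalization the median was 0.03. Of 28 genes of mitochondrial fatty acid oxidation, 0 were called by limma, 3 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (median 0.12, camera adjusted p = 0.00188, adjusted p = 0.695 with an estimated correlation). The 12 ventricular cardiomyocyte markers all had positive values (median 0.17, camera adjusted p = 8.17e-04, adjusted p = 0.695 with an estimated correlation), with 1 at an unadjusted p under 0.05. Of 27 genes of calcium handling and ion channels, 0 were called over all genes and 4 were called adjusted over the list alone (3 rose, 1 fell), among them Cacnb2 (0.57) and Kcna5 (0.51), subunits of calcium and potassium channels. This list had a median of 0.13 and a camera adjusted p of 0.00188, with an adjusted p = 0.578 with an estimated correlation. Glycolysis, pyruvate dehydrogenase with the citric acid cycle, and ketone body with branched-chain amino acid catabolism were also higher by camera (adjusted p = 0.0156, 0.0218 and 0.0218), and none of these held with an estimated correlation, where the lowest adjusted p of any list was 0.578.

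Camera with the preset correlation placed immune lists below other genes in ad libitum hearts, which was also lost with an estimated correlation, so a fall of these lists was not shown. The 18 macrophage markers had a median of -0.35 (camera adjusted p = 1.12e-05, adjusted p = 0.578 with an estimated correlation). None was called over all genes, 7 had an unadjusted p under 0.05, and 2 fell adjusted over the list alone, Cd14 (-0.68), the lipopolysaccharide co-receptor, and Csf1r (-0.43), the receptor for macrophage colony-stimulating factor. The 18 genes of antigen presentation had a median of -0.26 (camera adjusted p = 1.31e-05, adjusted p = 0.578 with an estimated correlation), with 0 called over all genes, 6 at an unadjusted p under 0.05 and 3 fallen adjusted over the list alone. These 3 were the class II genes H2-Aa (-1.06) and H2-Eb1 (-0.95) and the invariant chain Cd74 (-0.91). The 26 interferon responsive genes had a median of -0.15 (camera adjusted p = 0.00322, adjusted p = 0.578 with an estimated correlation). None was called over all genes, 6 had an unadjusted p under 0.05, and 1, Rsad2 (-0.49), fell adjusted over the list alone. Fibroblast markers (median -0.24, camera adjusted p = 0.0156, adjusted p = 0.695 with an estimated correlation) and ribosomal protein genes (median -0.07, camera adjusted p = 0.0359, adjusted p = 0.819 with an estimated correlation) were placed lower by camera too.

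Targets of the fatty acid receptor PPAR-alpha did not pass the test in this comparison. Angptl4, a secreted inhibitor of lipoprotein lipase, had a value of -1.30 (adjusted p = 0.104) and Ucp3, a mitochondrial carrier linked to fatty acid use, -0.71 (adjusted p = 0.252). In the circadian clock list, Nr1d2, a clock repressor, fell by 0.56 (adjusted p = 0.0365), and 7 of 23 genes passed adjusted over the list alone (2 rose, 5 fell). The list as a whole was not called by camera (adjusted p = 0.081). Fry called 0 of the 46 lists here, against 12 by camera at the preset correlation (7 higher, 5 lower; 3 and 5 after quantile normalization, 3 and 4 with the atrial covariate), and other splits of the same arrays gave up to 13. At an unadjusted p under 0.05, 1374 genes differed, against 668 expected with no difference.

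Leptin treated hearts were compared with ad libitum ob/ob hearts to see what leptin with its lower food intake changes. The largest rise and the largest fall were in clock genes. Dbp, a transcription factor driven directly by the clock, rose from a signal of 113 ± 17.6 to 556 ± 173 (2.21 ± 0.26, adjusted p = 5.81e-04). Arntl, the clock's core activator, fell from 189 ± 11.8 to 59.2 ± 11.7 (-1.61 ± 0.15, adjusted p = 1.21e-04; SD, n = 4 ad libitum and 5 leptin). Its other probe set above the filter had the opposite sign and was not called. Ppargc1a rose by 0.69 ± 0.11 to a signal of 919 ± 74.1 (adjusted p = 0.00866), and G0s2 rose by 0.71 (adjusted p = 0.0139). In total 86 genes were called, 54 higher and 32 lower with leptin.

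Among the 8 largest rises were Clec1b (1.80), Aldh1a2 (1.62), Upp1 (1.34), which breaks down uridine, Ifitm1 (1.22) and Tspan4 (1.06), a tetraspanin. The class II antigen presentation genes H2-Aa (1.16) and H2-Eb1 (1.08) also rose. Genes that fell included Ddit4 (-1.60), a stress-induced inhibitor of the growth kinase mTORC1, Col5a3 (-1.30), Cacng6 (-1.03), Epha4 (-0.96), an ephrin receptor, and Fcna (-0.78), a ficolin of innate immunity. Mettl11b (-1.22) and Tmem150c (-0.91) fell too. Of the 21 named genes called here, 13 stayed called whichever array of the 2 groups was left out, among them Dbp, Arntl, Ppargc1a, Ddit4, Col5a3, Cacng6 and Tspan4. The exceptions were Aldh1a2, Clec1b, Fcna, G0s2, H2-Aa, H2-Eb1, Mettl11b and Rsad2.

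In the circadian list of 23 genes, 5 rose and 1 fell, and 14 were called adjusted over the list alone (11 rose, 3 fell). Beside Dbp, the rises included Nr1d2 (0.76) and Per3 (0.77), which belong to the repressing arm of the clock. The list's median was 0.23 (camera adjusted p = 0.00129, adjusted p = 0.109 with an estimated correlation, fry adjusted p = 0.00394). Camera with the preset correlation also placed ribosomal protein genes above other genes, which fry did not call. Of 36 members 34 had a positive value, 0 were called over all genes by limma, 22 had an unadjusted p under 0.05, and 19 passed adjusted over the list alone (18 rose, 1 fell), such as Rpsa (0.45) and Rps19 (0.37). Both passed over all genes without leptin replicate 3 (adjusted p = 0.0299 and 0.0329). The median was 0.22 and the camera adjusted p was 4.44e-12, with an adjusted p = 0.522 with an estimated correlation.

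Of 18 genes of antigen presentation 2 rose, and 7 rose adjusted over the list alone, among them Cd74 (0.82) and the immunoproteasome subunit Psmb10 (0.45). The list had a median of 0.32 (camera adjusted p = 2.69e-07, adjusted p = 0.48 with an estimated correlation). The 26 interferon responsive genes had a median of 0.13, with 1 risen, the antiviral gene Rsad2 (0.55), and 5 risen adjusted over the list alone (camera adjusted p = 0.00129, adjusted p = 0.522 with an estimated correlation). Macrophage markers had a median of 0.26, with 0 of 18 called by limma, 7 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 5.82e-04, adjusted p = 0.701 with an estimated correlation). Fatty acid oxidation genes were not called as a list or singly, and 0 of 28 had an unadjusted p under 0.05. Angptl4 (0.93, adjusted p = 0.165), Ucp3 (0.70, adjusted p = 0.161) and Plin2, the lipid droplet coat protein (0.38, adjusted p = 0.18), did not pass the test. Without leptin replicate 5, Angptl4 (1.20, adjusted p = 0.0381) and Ucp3 (0.90, adjusted p = 0.0323) passed it. Myh7, the slow myosin heavy chain, had a value of 1.26 (adjusted p = 0.15) and passed without leptin replicate 4 (1.58, adjusted p = 0.0368).

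Camera called 5 of 46 lists, all higher, and fry called 2. After quantile normalization camera called 5 higher and 4 lower. Other splits of the same arrays gave up to 22 lists by camera, so chance could not be excluded for that number. The number of genes called was 42, 37 and 50 without ad libitum replicate 2, 3 or 4 and 47 and 35 without leptin replicate 1 or 2. Without leptin replicate 5, camera called 10 lists.

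Calorie restricted hearts were compared with ad libitum ob/ob hearts, which asks what the same lowering of food intake does without leptin. Of the genes that respond to fatty acids through PPAR-alpha 13 of 23 rose, and 24 of 46 genes of the extracellular matrix, 6 of 18 of antigen presentation and 7 of 26 of the interferon response fell. Camera called these 4 lists, and their adjusted p were 0.0852, 0.0852, 0.187 and 0.0852 with an estimated correlation. Angptl4 rose from a signal of 108 ± 19 to 626 ± 140 (2.47 ± 0.29, adjusted p = 1.51e-04) and Ucp3 from 184 ± 25.9 to 661 ± 129 (1.80 ± 0.22, adjusted p = 1.65e-04; SD, n = 4 ad libitum and 5 restricted). Col3a1, a fibrillar collagen, fell from 818 ± 182 to 137 ± 45.8 (-2.57 ± 0.37, adjusted p = 6.81e-04). Nppb, the natriuretic peptide released by a loaded ventricle, fell from 2407 ± 587 to 645 ± 255 (-2.0 ± 0.35, adjusted p = 0.00335). In total 725 genes were called, 328 higher and 397 lower.

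**Figure D2:**
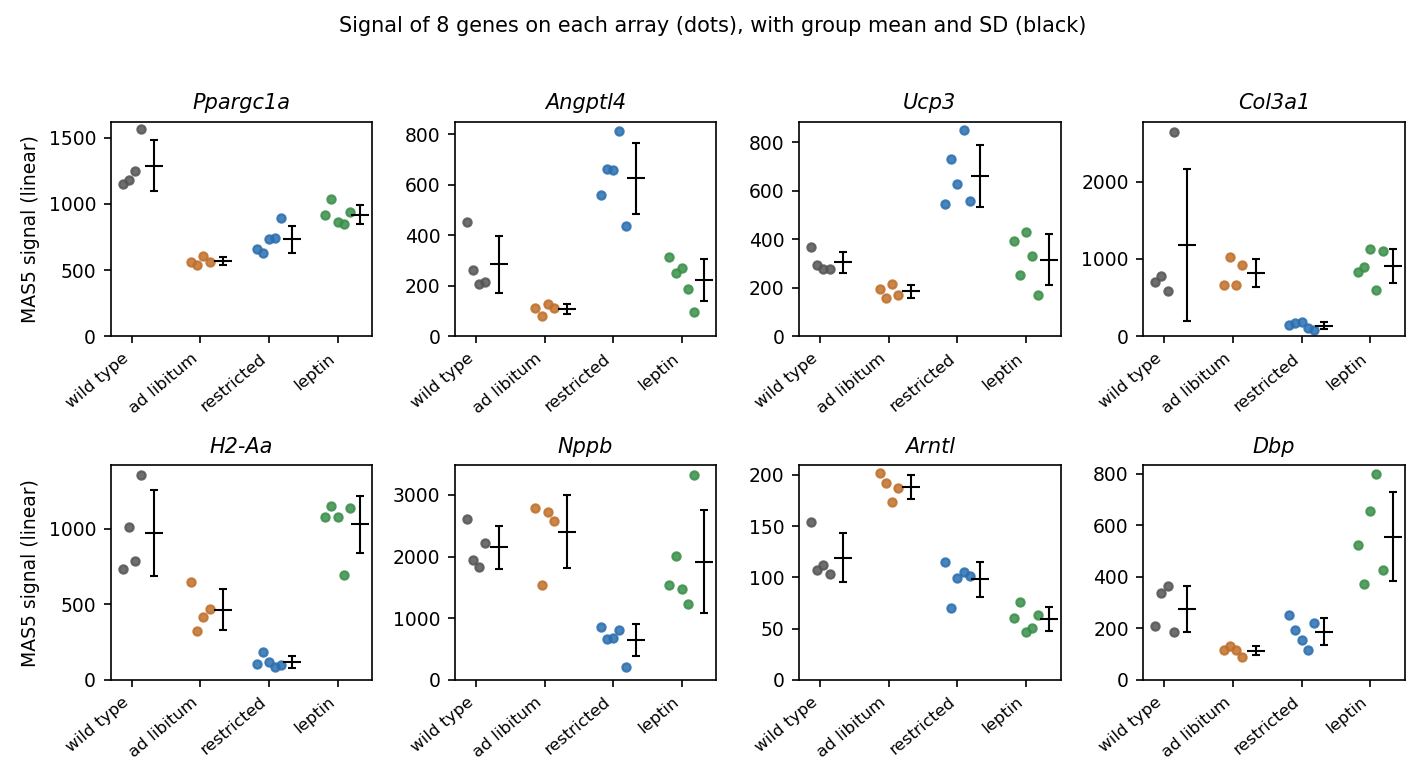
MAS5 signal (linear scale) of 8 genes on each of the 18 arrays, 1 point per array, with the mean and SD of each group. Angptl4 and Ucp3 were highest in the calorie restricted group (means 626 and 661), Col3a1, H2-Aa and Nppb were lowest there (137, 118 and 645), and Dbp was 113 in ad libitum and 556 in leptin treated hearts.

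The other genes among the 8 largest rises were Chrna2 (2.10), a nicotinic receptor subunit, Acot1 (2.0), a thioesterase that releases fatty acids from acyl-CoA, Clec1b (1.84), Arrdc4 (1.60), an arrestin family protein that restrains glucose uptake, Ing2 (1.51), a chromatin reader, and Cirbp (1.46), an RNA-binding protein induced by cold. The largest fall was in Aplnr, the receptor for the peptide apelin (-2.72 ± 0.23, adjusted p = 2.60e-05). H2-Aa (-1.94), Pcdh12 (-1.88), an endothelial protocadherin, P2ry6 (-1.87), a nucleotide receptor, Epn3 (-1.85) and Cdk1 (-1.79), the mitotic kinase, fell as well. All 16 stayed called whichever single array of the 2 groups was left out. Cdk1 was no longer called without calorie restricted replicates 2 and 3, and Cdk1, Chrna2 and Epn3 lost their call with the atrial marker signal as a covariate. P2ry6 and Cdk1 had restricted signals under the pseudocount (means 4.76 and 3.88), so the sizes of their changes depend on it.

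Of 23 PPAR-alpha responsive genes 13 rose and 0 fell, and 17 passed adjusted over the list alone (16 rose, 1 fell). Beside Angptl4, Ucp3 and Acot1, the rises included Mlycd (0.58), which degrades malonyl-CoA. The list's median was 0.47 (camera adjusted p = 5.52e-14, adjusted p = 0.0852 with an estimated correlation). In mitochondrial fatty acid oxidation 5 of 28 genes rose and 0 fell, and 10 passed adjusted over the list alone (8 rose, 2 fell). Examples were Cpt1a (0.68), the gatekeeper of fatty acid entry into mitochondria, Eci2 (0.56) and Slc25a20 (0.47), the carnitine-acylcarnitine carrier. The median was 0.17 (camera adjusted p = 1.98e-04, adjusted p = 0.399 with an estimated correlation). Of 15 peroxisomal genes 2 rose, Ehhadh (0.86) and Pex11a (0.52), and 6 passed adjusted over the list alone (camera adjusted p = 0.00314, adjusted p = 0.176 with an estimated correlation). In fatty acid uptake and activation 2 of 15 rose, Slc27a1 (0.79), a fatty acid transport protein, and Dbi (0.41), an acyl-CoA binding protein, and 1 fell, Acsl5 (-0.39; camera adjusted p = 0.0303, adjusted p = 0.38 with an estimated correlation).

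Genes of fat storage and fat breakdown both contained rises. In triacylglycerol synthesis 2 of 17 rose, Agpat2 (0.61) and Gpd1 (0.50), and 5 passed adjusted over the list alone (median 0.11, camera adjusted p = 0.00905, adjusted p = 0.148 with an estimated correlation). Dgat1, which catalyses the last step of the pathway, had a value of 0.29 (adjusted p = 0.0781) and Dgat2 0.32 (adjusted p = 0.231). Of 19 genes of lipolysis and lipid droplets 5 rose and 0 fell, and 6 passed adjusted over the list alone (5 rose, 1 fell). These included Cidea (0.85), which promotes lipid droplet growth, Pnpla2 (0.82), the lipase that begins triacylglycerol breakdown, and Plin4 (0.60), a droplet coat protein. That list was not called by camera (adjusted p = 0.0562). Plin2 had a value of 0.18 (adjusted p = 0.49) and Cd36, a fatty acid importer, 0.23 (adjusted p = 0.142). Pdk4, which restrains glucose oxidation, rose by 0.86 (adjusted p = 0.0341), while Ppara and Ppargc1a had values of -0.33 (adjusted p = 0.268) and 0.36 (adjusted p = 0.0679).

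Of 46 genes of the extracellular matrix 24 fell and 1 rose, and 27 passed adjusted over the list alone (1 rose, 26 fell). Col6a3 (-1.42), Serpinh1 (-1.26), the collagen chaperone, Col6a2 (-1.22) and Col4a1 (-1.08), a basement membrane collagen, were among those with the smallest p. The median was -0.52 (camera adjusted p = 3.05e-14, adjusted p = 0.0852 with an estimated correlation). Of 14 fibroblast markers 8 fell, such as Col1a1 (-1.69), Pi16 (-1.36) and Lum (-1.07), and 8 adjusted over the list alone (median -0.54, camera adjusted p = 3.30e-06, adjusted p = 0.284 with an estimated correlation). Endothelial markers were lower to a smaller extent, with a median of -0.20 and 2 of 14 fallen, Kdr (-0.64) and Tie1 (-0.56; camera adjusted p = 0.00845, adjusted p = 0.306 with an estimated correlation). Smooth muscle and pericyte markers had a median of 0.03 and were not called as a list (camera adjusted p = 0.93). In hypoxia and angiogenesis 6 of 28 fell and 2 rose, with Aplnr, Egln3 (-1.19) and Nrp1 (-0.48) lower and Angpt1 (0.87) higher (camera adjusted p = 0.00905, adjusted p = 0.0852 with an estimated correlation).

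Of 26 interferon responsive genes 7 fell, and 18 fell adjusted over the list alone. Rsad2 (-0.97) and Ifit1 (-0.69), both antiviral effectors, and Irf9 (-0.61), a transcription factor of the pathway, were among them (median -0.46, camera adjusted p = 1.11e-10, adjusted p = 0.0852 with an estimated correlation). In antigen presentation 6 of 18 fell, including Cd74 (-1.34), H2-Ab1 (-1.14) and B2m (-0.63), and 8 fell adjusted over the list alone (median -0.34, camera adjusted p = 1.20e-06, adjusted p = 0.187 with an estimated correlation). Of 18 macrophage markers 4 fell, C1qb (-0.75), Tyrobp (-0.71), Adgre1 (-0.60) and Csf1r (-0.41), and 10 fell adjusted over the list alone (median -0.46, camera adjusted p = 2.14e-05, adjusted p = 0.314 with an estimated correlation). Each of these 4 was close to the threshold and lost its call without any of 7 or 8 of the 9 single arrays, with adjusted p of up to 0.134.

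Some genes of cell division and protein folding fell, and camera called their lists only with the preset correlation. In the cell cycle list 5 of 26 fell, among them the D-type cyclins Ccnd2 (-0.62) and Ccnd1 (-0.52), and 7 passed adjusted over the list alone (1 rose, 6 fell; camera adjusted p = 7.26e-04, adjusted p = 0.0852 with an estimated correlation). Of 28 heat shock and chaperone genes 4 fell, such as Hsp90aa1 (-0.55) and Dnajb4 (-0.45), and 12 passed adjusted over the list alone (1 rose, 11 fell; camera adjusted p = 0.00433, adjusted p = 0.396 with an estimated correlation). Of 30 genes of the unfolded protein response 3 fell, Manf (-0.67), Sdf2l1 (-0.66) and Dnajc3 (-0.46), and 3 fell adjusted over the list alone (camera adjusted p = 0.00905, adjusted p = 0.34 with an estimated correlation). Of 20 genes of ketone body and branched-chain amino acid catabolism 3 fell, and 5 passed adjusted over the list alone. The 3 that fell were Bdh1 (-1.31), Oxct1 (-0.46), both enzymes of ketone body use, and Dbt (-0.60), a subunit of the branched-chain ketoacid dehydrogenase (camera adjusted p = 0.00156, adjusted p = 0.399 with an estimated correlation).

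Of 35 glucocorticoid responsive genes 3 rose, among them Sult1a1 (0.82), and 5 passed adjusted over the list alone (camera adjusted p = 0.00601, adjusted p = 0.327 with an estimated correlation). Camera also placed ribosomal protein genes (median 0.15, adjusted p = 2.32e-05, adjusted p = 0.399 with an estimated correlation), oxidative phosphorylation (median 0.08, adjusted p = 0.00393, adjusted p = 0.77 with an estimated correlation) and uncoupling and thermogenesis (median 0.11, adjusted p = 0.0114, adjusted p = 0.176 with an estimated correlation) above other genes, as it did pyruvate dehydrogenase with the citric acid cycle (adjusted p = 0.00905, adjusted p = 0.424 with an estimated correlation). In the clock list 3 genes rose, including Per2 (0.88) and Tef (0.56), and 1 fell, Arntl (-0.92), while camera did not call the list (adjusted p = 0.0799).

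The 10 atrial cardiomyocyte markers all had positive values in restricted hearts (median 1.25, camera adjusted p = 4.17e-04, adjusted p = 0.284 with an estimated correlation). None was called over all genes by limma, 6 had an unadjusted p under 0.05 and 6 rose adjusted over the list alone, and the highest signals lay in replicates 2 and 3. Without these 2 arrays 356 genes were called in this comparison. Of the 77 named genes called here, 24 then lost their call, among them Gpd1, Agpat2, Ehhadh, Pdk4, Acsl5, Oxct1, Manf, Kdr, Tie1, Sult1a1 and the 4 macrophage markers. With the atrial marker signal as a covariate 323 genes were called and 29 of the 77 lost their call, among them also Cpt1a and Pi16. Leaving out single arrays ended the call of 20 of the 77, among them Pdk4, Acsl5 and Tie1 (7, 7 and 8 of the 9 arrays), Irf9 and Kdr (4 and 3 arrays) and Manf (adjusted p = 0.0502 without ad libitum replicate 4). Camera called 22 of 46 lists in this comparison (11 higher, 11 lower; 6 and 12 after quantile normalization) and fry called 20. The number of genes called was 440 without ad libitum replicate 3 and 443 without ad libitum replicate 4.

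**Figure D3:**
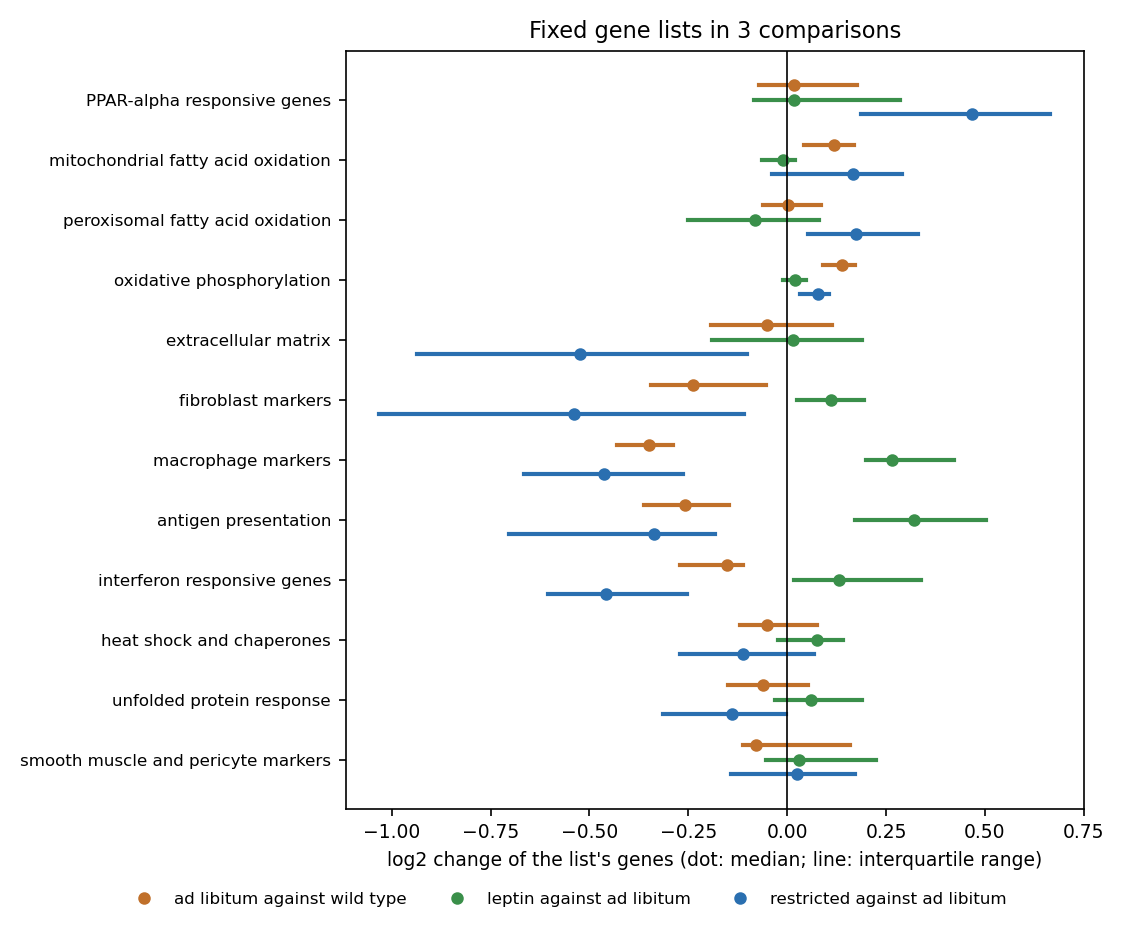
Median log2 change (points) and interquartile range (lines) of the members of 12 gene lists, for ad libitum against wild type, leptin against ad libitum and calorie restricted against ad libitum. In calorie restricted hearts the extracellular matrix (-0.52) and interferon lists (-0.46) lie below 0 and the PPAR-alpha list (0.47) above it.

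Leptin treated hearts were compared directly with calorie restricted hearts, the 2 groups with matched food intake. This comparison held the largest number of called genes, 1819, of which 1055 were higher and 764 lower with leptin. Aplnr had a signal of 509 ± 84.2 with leptin and 35.0 ± 6.81 with restriction (3.68 ± 0.22, adjusted p = 1.03e-07), and H2-Aa 1027 ± 191 and 118 ± 37.5 (3.09 ± 0.22, adjusted p = 7.64e-07; SD, n = 5 each). Col3a1 was 910 ± 218 and 137 ± 45.8 (2.71 ± 0.34, adjusted p = 1.04e-04). Angptl4 was lower with leptin, at 224 ± 83.7 against 626 ± 140 (-1.53 ± 0.28, adjusted p = 0.00173).

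The remaining genes among the 8 most raised by leptin over restriction were Aldh1a2 (2.71), Ano10 (2.19), a member of the anoctamin family, Cd74 (2.16), Mpeg1 (2.04), a macrophage perforin-like protein, and H2-Eb1 (1.97). The lower genes were Chrna2 (-2.57), Cirbp (-2.05), Arrdc4 (-1.85), Gnmt (-1.80), a glycine methyltransferase, Acot1 (-1.70), Psat1 (-1.61), which acts in serine synthesis, and Kif15 (-1.58), a mitotic kinesin. All 16 stayed called whichever single array of the 2 groups was left out and without calorie restricted replicates 2 and 3. Aldh1a2 had a restricted signal of 2.20 ± 1.14, under the pseudocount, so the size of its difference from other groups depends on the pseudocount.

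Many immune and stromal genes were higher with leptin. Of 26 interferon responsive genes 15 were higher and 0 lower, and all 26 had a positive value, with Rsad2 at 1.52, Ifit1 at 1.03 and Ifit2 at 1.01. Adjusted over the list alone, 19 passed (median 0.60, camera adjusted p = 8.67e-14, adjusted p = 0.0283 with an estimated correlation). In antigen presentation 12 of 18 were higher, and 15 adjusted over the list alone, including H2-Ab1 (1.71; median 0.68, camera adjusted p = 1.13e-12, adjusted p = 0.0635 with an estimated correlation). Of 18 macrophage markers 12 were higher, such as C1qb (1.23), Tyrobp (1.15) and Adgre1 (0.98), and 14 adjusted over the list alone (median 0.78, camera adjusted p = 1.86e-09, adjusted p = 0.15 with an estimated correlation). In the extracellular matrix 24 of 46 were higher and 1 lower, with Sparc (1.28), Serpinh1 (1.19) and Col4a1 (1.18) among them, and 28 passed adjusted over the list alone (median 0.52, camera adjusted p = 1.96e-11, adjusted p = 0.12 with an estimated correlation). Of 14 fibroblast markers 9 were higher, among them Pi16 (1.47) and Dpt (0.80), and 9 adjusted over the list alone (median 0.76, camera adjusted p = 3.28e-07, adjusted p = 0.224 with an estimated correlation). Endothelial markers had a median of 0.31 with 4 of 14 higher, including Tie1 (0.83) and Tek (0.56; camera adjusted p = 1.56e-04, adjusted p = 0.12 with an estimated correlation).

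Many genes of fatty acid use were lower with leptin than with restriction. Of 23 PPAR-alpha responsive genes 14 were lower and 0 higher, including Ucp3 (-1.11), Slc25a42 (-0.79) and Gpd1 (-0.72), and 16 passed adjusted over the list alone (median -0.45, camera adjusted p = 1.21e-09, adjusted p = 0.12 with an estimated correlation). In mitochondrial fatty acid oxidation 9 of 28 were lower, such as Cpt1a (-0.66), Eci2 (-0.54) and Acaa2 (-0.44), 2 were higher, and 14 passed adjusted over the list alone (2 higher, 12 lower; camera adjusted p = 3.08e-04, adjusted p = 0.489 with an estimated correlation). Of 15 peroxisomal genes 6 were lower, among them Pex11a (-0.69) and Pecr (-0.61), and 9 passed adjusted over the list alone (1 higher, 8 lower; camera adjusted p = 0.00148, adjusted p = 0.12 with an estimated correlation). Cidea (-0.71) and Pnpla2 (-0.70) were lower with leptin and G0s2 (0.97) was higher. Dgat1 (-0.40, adjusted p = 0.00565) and Cd36 (-0.27, adjusted p = 0.0364) were lower, as were Dgat2 (-0.44, adjusted p = 0.0409) and Scd1 (-0.74, adjusted p = 0.0318), the stearoyl-CoA desaturase. The calls of Cd36, Dgat2, Scd1 and Ppargc1a (0.33) were lost without any of 6 to 8 of the 10 single arrays, with adjusted p of up to 0.105. That of Acadm (-0.28) was lost without calorie restricted replicate 4 or leptin replicate 1 or 5, with adjusted p of up to 0.0592. All 5 were lost without calorie restricted replicates 2 and 3. Ppara was higher with leptin (0.58, adjusted p = 0.0163), a call that was also lost without those 2 arrays.

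Nppb was higher with leptin, at 1915 ± 837 against 645 ± 255 (1.61 ± 0.33, adjusted p = 0.00432), and Myh7 was higher by 1.23 (adjusted p = 0.0315), a call lost without the 2 arrays with atrial signal and without any of 7 single arrays (adjusted p up to 0.0826). Of 28 heat shock genes 11 were higher, such as Hsph1 (1.18) and Hsp90aa1 (0.70), and 15 passed adjusted over the list alone (14 higher, 1 lower; camera adjusted p = 2.42e-04, adjusted p = 0.251 with an estimated correlation). Of 30 unfolded protein response genes 8 were higher, including Manf (0.83) and Pdia3 (0.57), and 10 passed adjusted over the list alone (9 higher, 1 lower; camera adjusted p = 3.56e-04, adjusted p = 0.188 with an estimated correlation). In the cell cycle 7 of 26 were higher, among them Cdk1 (1.95) and Top2a (1.17), and 8 adjusted over the list alone (camera adjusted p = 3.36e-04, adjusted p = 0.0635 with an estimated correlation). Hypoxia and angiogenesis had 7 of 28 higher and 2 lower (camera adjusted p = 0.0075, adjusted p = 0.0635 with an estimated correlation), and glucocorticoid responsive genes 7 of 35 lower and 1 higher, with Sult1a1 (-1.27) and Errfi1 (-0.63) lower (camera adjusted p = 0.00104, adjusted p = 0.232 with an estimated correlation). Lower with leptin were also the lists of pyruvate dehydrogenase with the citric acid cycle (1 of 29 lower, camera adjusted p = 0.0149, adjusted p = 0.503 with an estimated correlation) and atrial markers (2 of 10 lower, median -0.85, camera adjusted p = 0.023, adjusted p = 0.489 with an estimated correlation). Of the clock genes, Timeless (1.91), Dbp (1.54) and Nr1d2 (0.43) were higher and Arntl (-0.68) lower.

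Camera called 16 of 46 lists (10 higher, 6 lower) and fry 22, and other splits of the same arrays gave up to 25 lists by camera. The number of genes called was 1020 without calorie restricted replicates 2 and 3.

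Leptin treated hearts were also compared with wild type hearts, to see what differed from lean animals after treatment. Kcnk1 was the only gene called of 13359, at 126 ± 12.1 with leptin and 49.8 ± 9.37 in wild type (1.27 ± 0.13, adjusted p = 3.21e-04; SD, n = 5 and 4). The next genes were not called: Klhl40, a muscle protein of the sarcomere, had a value of 0.78, Lhx6 0.67, Has1, a hyaluronan synthase, 1.19 (adjusted p = 0.158 each) and Car8 0.45 (adjusted p = 0.178). On the lower side Arntl had -0.95 (adjusted p = 0.0657), Zfp526 -0.67 (adjusted p = 0.124), and Ell2 and Dut -0.66 and -0.45 (adjusted p = 0.158 each). Arntl passed without leptin replicate 2 (adjusted p = 0.0243) or wild type replicate 4 (adjusted p = 0.046). Ppargc1a had -0.48 (adjusted p = 0.213). At an unadjusted p under 0.05, 1335 genes differed, against 668 expected with no difference. A call missing here does not show that the groups were alike. The count was 2 without leptin replicate 2, 2 without wild type replicate 3 and 5 without wild type replicate 4.

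Camera placed 7 lists above other genes in leptin treated hearts, with 0 members called by limma in any of them and fry calling 0 lists. In oxidative phosphorylation 75 of 76 values were positive, 13 had an unadjusted p under 0.05 and the median was 0.16, with Uqcr10 at 0.28 and Cox8a at 0.19 (camera adjusted p = 5.60e-15, adjusted p = 0.734 with an estimated correlation). Ribosomal protein genes had a median of 0.15 and 13 of 36 at an unadjusted p under 0.05 (camera adjusted p = 1.30e-07, adjusted p = 0.734 with an estimated correlation). Ventricular cardiomyocyte markers had a median of 0.20, with Myl2 at 0.24 and Ryr2 at 0.25, and 3 of 12 at an unadjusted p under 0.05 (camera adjusted p = 5.33e-05, adjusted p = 0.734 with an estimated correlation). Endothelial markers had a median of 0.24, with Tek at 0.37, and 3 of 14 at an unadjusted p under 0.05 (camera adjusted p = 6.73e-04, adjusted p = 0.734 with an estimated correlation). Fatty acid oxidation (median 0.09, 1 of 28 at an unadjusted p under 0.05, camera adjusted p = 0.0159), calcium handling (median 0.15, 7 of 27, adjusted p = 0.0285) and antioxidant defence (median 0.07, 6 of 34, adjusted p = 0.0285) followed, with adjusted p of 0.814, 0.734 and 0.765 with an estimated correlation. After quantile normalization 1 list was called, and 4 with the atrial covariate, so most of these calls depended on the processing. Other splits of the same arrays gave up to 19 lists. The number of lists was 4 without leptin replicate 1, 4 without leptin replicate 4 and 11 without wild type replicate 4.

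Calorie restricted hearts differed from wild type hearts in 1504 genes, 670 higher and 834 lower. Aplnr was 35.0 ± 6.81 with restriction and 392 ± 117 in wild type (-3.28 ± 0.23, adjusted p = 7.71e-07), and H2-Aa 118 ± 37.5 and 970 ± 283 (-2.99 ± 0.24, adjusted p = 1.68e-06; SD, n = 5 and 4). Aldh1a2 (-3.18) and Col3a1 (-2.82) fell too. The largest rises were Kcnk1 (2.14), Acot1 (2.01), Chrna2 (1.87) and Cyp2d22 (1.84). Ppargc1a fell by 0.81 (adjusted p = 2.36e-04), Ppara by 0.76 (adjusted p = 0.00519) and Nppb by 1.86 (adjusted p = 0.00287). Socs3, a target and brake of leptin signalling, fell by 0.78 (adjusted p = 0.0254), a call lost without calorie restricted replicate 5 (adjusted p = 0.0619) and without wild type replicate 1 (0.0811) or 4 (0.0748). Ucp3 rose by 1.10, Angptl4 by 1.17, Dgat1 by 0.48 and Cd36 by 0.41 (adjusted p = 0.00371, 0.0168, 0.00272 and 0.00531). The call of Angptl4 was lost without calorie restricted replicates 2 and 3 (adjusted p = 0.0856) and without wild type replicate 3 (0.0543) or 4 (0.0554).

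Of 26 interferon responsive genes 16 fell, and 20 adjusted over the list alone, with Rsad2 at -1.46 and Ifit1 at -0.96 (median -0.65, camera adjusted p = 6.31e-13, adjusted p = 0.0369 with an estimated correlation). In antigen presentation 9 of 18 fell and 12 adjusted over the list alone, with Cd74 at -2.26 (median -0.46, camera adjusted p = 1.56e-11, adjusted p = 0.096 with an estimated correlation). Of macrophage markers 11 of 18 fell, and 14 adjusted over the list alone, among them C1qb (-1.19) and Adgre1 (-1.02; camera adjusted p = 2.86e-11, adjusted p = 0.145 with an estimated correlation). In the extracellular matrix 21 of 46 fell, such as Serpinh1 (-1.32) and Sparc (-1.10), and 26 passed adjusted over the list alone (1 rose, 25 fell; camera adjusted p = 7.91e-12, adjusted p = 0.145 with an estimated correlation). Of fibroblast markers 9 of 14 fell, with Pi16 at -2.47 (median -0.85, camera adjusted p = 4.38e-08, adjusted p = 0.22 with an estimated correlation). PPAR-alpha responsive genes rose in 16 of 23 and fell in 0, 17 adjusted over the list alone (median 0.47, camera adjusted p = 1.41e-12, adjusted p = 0.096 with an estimated correlation). In mitochondrial fatty acid oxidation 13 of 28 rose, with Cpt1a at 0.87 and Eci2 at 0.53, and 19 passed adjusted over the list alone (18 rose, 1 fell; camera adjusted p = 4.38e-08, adjusted p = 0.252 with an estimated correlation). In oxidative phosphorylation 3 of 76 rose, Sdhd (0.37), Uqcrc1 (0.29) and Ndufb6 (0.29), and 22 adjusted over the list alone. Each of these 3 calls was lost without any of 6 or 7 of the 9 single arrays (median 0.21, camera adjusted p = 5.81e-12, adjusted p = 0.375 with an estimated correlation).

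Heat shock genes fell in 8 of 28, including Hsph1 (-1.46; camera adjusted p = 0.00346, adjusted p = 0.359 with an estimated correlation), and unfolded protein response genes in 8 of 30, including Sdf2l1 (-0.81; camera adjusted p = 0.00153, adjusted p = 0.25 with an estimated correlation). Glucocorticoid responsive genes rose in 7 of 35 and fell in 1, with Sult1a1 at 1.49 and Fkbp5 at 0.84 (camera adjusted p = 2.70e-04, adjusted p = 0.22 with an estimated correlation). In antioxidant defence 6 of 34 rose and 2 fell, with Gsta4 at 1.26 and Nqo1 at 0.57 (camera adjusted p = 0.00408, adjusted p = 0.362 with an estimated correlation). Among contractile and hypertrophy genes 3 of 29 rose and 2 fell, Acta1, the skeletal actin re-expressed in hypertrophy, by 1.79 and Nppb (camera adjusted p = 0.0209, adjusted p = 0.314 with an estimated correlation). Camera called 18 lists (10 higher, 8 lower; 4 and 8 after quantile normalization) and fry 26, and other splits of the same arrays gave up to 21 lists by camera. The number of genes called was 885 without calorie restricted replicates 2 and 3.

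The last question was whether either treatment moved the 40 genes that separated ad libitum ob/ob from wild type hearts back towards wild type. With leptin all 40 had a change opposite in sign to the ob/ob difference, and 23 of them were called in that direction and 0 in the other. With calorie restriction 27 of 40 (67.5%) were opposite, 11 of them called, and 3 were called in the same direction as the ob/ob difference. Over the genes called with 1 array left out, this share ran from 44.4% (without wild type replicate 3) to 80% (without ad libitum replicate 3). The 23 genes called opposite with leptin included Ppargc1a, G0s2, Nr1d2, Col5a3, Cacng6, Tspan4 and Kcnk1. Kcnk1 fell with leptin by 0.69 (adjusted p = 0.0199) and remained above wild type. Cyp2d22 rose further under restriction (0.97, adjusted p = 6.73e-04).

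Because the ad libitum arrays enter both differences, opposite signs arise with no effect. Calls in the opposite direction are favoured for the same reason, so the 23 and 11 called genes alone show no return. Simulated unchanged groups gave a mean share of 99.7% opposite (92.5% to 100%) for leptin. For restriction they gave 99.6% (95% to 100%), above the observed 67.5%. These draws also held no ob/ob difference, so their 40 genes were picked on noise alone. Genes with a real ob/ob difference are pushed to opposite signs less, so the simulated shares and slopes are no expectation for the real 40. The share of 100% alone still shows no return, since the shared arrays favour it. The slope of the leptin change on the ob/ob difference was -0.70 (unchanged -0.50, range -0.65 to -0.33), and that of restriction -0.21 (unchanged -0.50, range -0.67 to -0.31), so the leptin slope lay below its range and the restriction slope above. Neither position held whichever array was left out. The leptin slope was then -0.73 to -0.44 (without wild type replicate 4) and that of restriction -0.42 (without wild type replicate 2) to -0.037. When different ad libitum arrays were used to define the ob/ob difference and to measure the treatment, over 6 arrangements, the 40 highest ranked genes were chosen anew each time, of which only 2 to 7 passed the test. For these sets the share for leptin averaged 80.4% (70% to 87.5%) with a slope of -0.36 (-0.43 to -0.20). For restriction it averaged 49.6% (32.5% to 57.5%) with a slope of -0.01 (-0.13 to 0.10).

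The direct comparison of leptin with restriction shares no ad libitum array. Of the 40 genes, 32 (80%) were on the wild type side with leptin, 21 of them called and 1 called on the other side. Of all 13359 genes 57.1% were on the wild type side. Fry gave a p of 1.71e-09 for a net move of the 40 genes towards wild type, a test that does not compare them with other genes. Other splits of the treated arrays gave shares of up to 92.5%, while their mean change reached 0.350 at most, against 0.454 for the real groups. The genes called on the wild type side included Aldh1a2, Ms4a6d, G0s2 and Kcnk1. For 13 of the 40 genes, these among them, restricted hearts lay further from wild type than ad libitum hearts did. The comparison thus counts moves away under restriction and past wild type with leptin, not only returns. Without ad libitum replicate 3 only 5 genes defined the difference, the share was 60% and the fry p was 0.0889, so the move no longer passed.

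Over all genes, the ob/ob difference and the leptin change correlated at -0.53, equal to the -0.53 of unchanged groups, and their covariance was -0.0355 against -0.0260. The 25 genes lower in ob/ob and the 54 raised by leptin shared 17, against 0.101 for independent lists, and the 15 higher and 32 lowered shared 6, against 0.0359. The ob/ob difference and the restriction change correlated at -0.28 (unchanged -0.52, range -0.78 to -0.33, covariance -0.0210 against -0.0249). The 2 treatments' changes against ad libitum correlated at 0.28 (unchanged 0.55), with a covariance of 0.0223 against 0.0251. They shared 13 genes called higher, against 1.33 for independent lists, and 11 called lower, against 0.951. These overlaps count both real effects and the shared arrays. Against wild type, the 2 treatments correlated at 0.34 (unchanged 0.55, covariance 0.0286 against 0.0261). Each of the 4 covariances lay within the range of unchanged groups, which was -0.0487 to -0.0169, -0.0645 to -0.0153, 0.0136 to 0.0510 and 0.0123 to 0.0566 in the order given, so none set the real groups apart from unchanged ones. Of the 4 correlations, only that of the ob/ob difference with the restriction change lay outside its range.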

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

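The tests of the non-myocyte share, both tests of the clock genes and the test of shared variation in oxidative phosphorylation were chosen only after the results were seen. The test of atrial tissue was also chosen only after the data were seen, since the atrial signals led to it, though what it predicts was written before its result, and those of RNA quality, scaling and the splits were written before. For atrial tissue and RNA quality this holds for the matrix list, and the medians of the macrophage and interferon lists were added only after the results were seen. The values listed last are single arrays that stood far from the others of their group, by the gap to the nearest array relative to the group's range (Dixon's criterion). Of 1056 groups of values tested, over 258 genes and 6 quality measures, 77 (7.29%) were found, where chance gives about 1 in 20 (5%).

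Matrix, macrophage and interferon genes were lower as lists in calorie restricted than in ad libitum hearts by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.0852, 0.314 and 0.0852). A smaller share of every non-myocyte cell type would lower fibroblast and endothelial markers alike. Fibroblast markers fell further by 0.49 (difference -0.49, exact permutation p = 0.00794, the smallest that 4 against 5 arrays can give), and the difference to smooth muscle and pericyte markers was -0.736. Part of this was given by the pattern, since fibroblast markers such as Col1a1 and Col3a1 are matrix genes themselves. The test thus cannot tell a smaller cell share from lower collagen expression. Atrial tissue in calorie restricted replicates 2 and 3 would predict a smaller change without them, but the medians of the matrix, macrophage and interferon lists were then -0.60, -0.52 and -0.49, against -0.52, -0.46 and -0.46 with all arrays, though the 4 called macrophage markers lost their calls. With the 3' to 5' ratios as covariates the medians were -0.48, -0.40 and -0.45, which argues against RNA quality. A lower number of fibroblasts and macrophages, or lower expression within them, may underlie the change, and these data do not separate those.

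Clock genes differed between leptin treated and ad libitum hearts. A shift of all signals would move them all alike, so a score compared sets of 10 and 5. The first held Dbp, Tef, Hlf, Per1, Per2, Per3, Nr1d1, Nr1d2, Ciart and Bhlhe41. The second held Arntl, Clock, Npas2, Nfil3 and Cry1. Cry1 and Nfil3 are repressors, so the sets were not the clock's arms. The first set rose over the second by 1.80 (log2, exact permutation p = 0.00794, adjusted p = 0.0159 over 4 comparisons). If meal timing under restriction were the whole cause, the score was predicted to move mostly in restricted hearts. There it moved by 0.97 (exact permutation p = 0.00794), less than with leptin. This is not decisive, since a score at 1 time of day does not measure how far a phase shifted. The leptin treated mice also ate less. The score was -0.66 in ad libitum against wild type (exact permutation p = 0.0286) and 1.15 in leptin against wild type (exact permutation p = 0.0159, adjusted p = 0.0212). A shifted phase of the heart clock may be involved, but at 1 time of day phase and amplitude were not separated.

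Oxidative phosphorylation genes were higher as a list in ad libitum than in wild type hearts. The list's genes vary together between arrays of a group (estimated correlation 0.657), and with that correlation the adjusted p was 0.695. After quantile normalization the median was 0.0299, against 0.14 as deposited. Both values are consistent with array-to-array variation and scaling as the source of this small shift, and a rise in mitochondrial genes was not shown.

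Other splits of the arrays of each comparison were tested in the same way. Chance could be excluded for the gene number in leptin against ad libitum (86, highest other split 9) and against calorie restricted (1819, highest other 9). So it could for calorie restricted against ad libitum (725, highest other 262) and against wild type (1504, highest other 439). Each had 1 of 100 as large, the real one. It could not be excluded for leptin against wild type (1, highest other 1, 5 of 100). Nor could it for ad libitum against wild type (40, highest other 3), where 1 of 35 splits was the fewest possible. For the number of lists in calorie restricted against ad libitum, 3 of 100 splits called as many, the real one included (22, highest other 23). As another split called more, with no adjustment over the comparisons, chance was made unlikely there but not excluded. Chance could not be excluded for the number of lists in ad libitum against wild type (12, highest other 13, 3 of 35 splits), leptin against ad libitum (5, highest other 22, 59 of 100), leptin against calorie restricted (16, highest other 25, 27 of 100), leptin against wild type (7, highest other 19, 55 of 100) and calorie restricted against wild type (18, highest other 21, 12 of 100). Splits that call several times the real number of lists, as for leptin against ad libitum, point to lists that vary together between arrays.

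Calorie restricted replicate 4 held 14 of the 77 values: signals of Acadvl 5200, Asf1b 7.25, Ccnd3 391, Dnaja1 442, Ell2 285, Has1 24.4, Igtp 137, Mb 10005, Myl2 10029, Myl3 10468, Pi16 107, Tnni3 8482, Tnnt2 9743 and Uqcrb 9637, with Asf1b and Igtp low and the others high. Wild type replicate 4 held 11: Abhd5 259, Acadvl 3576, Col1a1 624, Col3a1 2646, Gbp2 181, Gpd1 227, H2-Ab1 357, Hyou1 272, Nrp1 974, Pnpla2 1471 and Rpl13a 3851, with Hyou1 and Nrp1 low and the others high. In the other wild type arrays the signals were Dnajb4 1548 (replicate 1), Clec1b 44.8 (replicate 2) and Chrna2 38.6 (replicate 3). Ad libitum replicate 1 had Myl7 438, Sln 98.1, Rpl13a 4018, Sdf2l1 61.4 and Tfb1m 198. Ad libitum replicate 2 had Clec1b 12.7, Echs1 2299, Ing2 32.4, Ndufv1 3344, Nppb 1537 and Slc27a1 468. Ad libitum replicate 3 had Ldha 4695, Tnni3 7332, Tnnt2 8419 and Uqcrc1 5711, and replicate 4 had Cacnb2 489, Fcgr3 68.0, Per3 26.8 and Tie1 231. Calorie restricted replicate 1 had Gbp2 89.0, Gsta4 1015, Lepr 48.0 and Rsad2 197, replicate 3 had Pnpla8 625, and replicate 5 had Aldh1a2 4.15, Ddit4 2054, Nr3c1 332 and Pccb 599.6. Leptin replicate 1 had Chrna2 20.2, replicate 2 had Bmp10 36.6, Ces1d 638, Klhl40 149, Myl7 264 and Sln 66.3, and replicate 3 had Arrdc4 46.5, Lpin2 129, Pecr 161 and Ppp1r3c 2291. Leptin replicate 4 had Egln3 1159, Fhl1 2410.4, Gbp2 113, H2-Aa 690.3, Myh7 264 and Pex11a 375, and replicate 5 had Foxo3 345, Mlycd 436, Nppa 2551, Plin5 1032 and Upp1 89.3.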

How the results depend on the processing

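The fits without calorie restricted replicates 2 and 3 and with the atrial marker signal as a covariate, and the leaving out of arrays for the quality measures, were chosen only after the data were seen; the other alternatives were planned. Of 11223 comparisons of named gene values with an alternative, 10305 stayed on their side of the threshold, among them 85 uncalled values that changed sign. Another 824 were no longer past it, 94 passed it newly and 0 called values changed sign. For genes, no scaling moved the share of higher calls by over 10 percentage points, but for lists quantile normalization did. A second probe set above the filter had the opposite sign, uncalled, for Arntl in leptin against ad libitum and Nr4a3 in ad libitum against wild type. The same held for Arrdc4 in leptin against calorie restricted and Dgat1 in calorie restricted against wild type. Signals near background limit what the arrays can resolve, since 16.7% to 22.7% of probe sets lay at or below the pseudocount. Where a value below differs from the one reported, the cause was not tested unless stated.

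Genes called in ad libitum against wild type (40) became 10 with the atrial covariate, 78 with a trended and robust prior, 25 with median centring, 13 with no filter, 8 with only the 2 groups fitted (fewer arrays estimate the spread) and 18 without calorie restricted replicates 2 and 3. Leptin against ad libitum (86) became 166 with the trended and robust prior, 132 with a filter at the 60th percentile (fewer genes tested), 54 with no filter (more genes tested) and 8 with only the 2 groups. Calorie restricted against ad libitum (725) became 323 with the atrial covariate, 355 with only the 2 groups and 356 without replicates 2 and 3 (fewer arrays). Leptin against calorie restricted (1819) became 1198 with the atrial covariate and 1020 without those 2 arrays. Leptin against wild type (1) became 3 with array weights, 3 with the trended and robust prior, 3 with every probe set, 2 with the filter at the 60th percentile and 2 without those 2 arrays. Calorie restricted against wild type (1504) became 979 with only the 2 groups and 885 without those 2 arrays.

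Lists called, in the order ad libitum against wild type (12), leptin against ad libitum (5), calorie restricted against ad libitum (22), leptin against calorie restricted (16), leptin against wild type (7) and calorie restricted against wild type (18), became 0, 0, 0, 1, 0 and 1 with the estimated correlation, where correlated list members widen the error. Fry called 0 lists in ad libitum against wild type, 2 in leptin against ad libitum and 0 in leptin against wild type. With the atrial covariate the first became 7 and leptin against wild type 4. With quantile normalization leptin against ad libitum became 9 (5 higher, 4 lower) and leptin against wild type 1. The split also moved in ad libitum against wild type (from 7 higher and 5 lower to 3 and 5), calorie restricted against ad libitum (from 11 and 11 to 6 and 12) and calorie restricted against wild type (from 10 and 8 to 4 and 8), so the number of lists called higher depends on the scaling.

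The replicate number as a block left 0, 0, 0, 370, 0 and 26 genes called by limma in the same order, where 1374, 1813, 2560, 3598, 1335 and 3277 genes had an unadjusted p under 0.05 without the block, and 11 lists in leptin against wild type with the replicate block. The numbers did not pair the arrays: same-numbered arrays of different groups correlated at a mean of -0.0211 (25 pairs, -0.181 to 0.345) and others at 0.00547 (96 pairs), and 2 of 18 arrays correlated best with their own number.

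With all genes in place of the 40, the share opposite to the ob/ob difference with leptin was 68.4%. With no filter the slope for calorie restriction was 0.0031, against -0.21. Leaving out 1 array at a time gave 5 to 27 genes for ad libitum against wild type, 35 to 88 for leptin against ad libitum, 440 to 738 for calorie restricted against ad libitum and 1 to 5 for leptin against wild type. It gave 5 to 10 lists for leptin against ad libitum, 4 to 11 for leptin against wild type and a share on the wild type side of 60% to 86.7% for leptin against calorie restriction. The number of quality differences called was 0 of 36 by exact permutation tests under each alternative, but with so few arrays per group a single difference could not have passed, so this count says little about how stable the quality measures are.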

Other observations

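The mean change towards wild type was tested only after the share was seen. The tests of interferon and macrophage genes, of genes near Lep and of the share were written before. Nppb was 2151 ± 348 in wild type, 2407 ± 587 in ad libitum, 645 ± 255 in calorie restricted and 1915 ± 837 in leptin treated hearts, whereas Myh7 was 399 ± 137, 289 ± 127, 287 ± 112 and 701 ± 254 and Myh6, the fast myosin, 7011 ± 382, 7706 ± 486, 8360 ± 860 and 7758 ± 899 (SD, n = 4, 4, 5 and 5). Nppa, which is also an atrial transcript, was 1467 ± 343, 860 ± 310, 3014 ± 2408 and 1699 ± 492 in the same order, with 5724 and 5566 in calorie restricted replicates 2 and 3. Kcnk1 was 49.8 ± 9.37 in wild type, 208 ± 33.2 in ad libitum, 235 ± 27.2 in calorie restricted and 126 ± 12.1 in leptin treated hearts, higher in each ob/ob group than in wild type. Aldh1a2, which makes retinoic acid, was 64.2 ± 24.7, 13.2 ± 10.9, 2.20 ± 1.14 and 43.1 ± 8.37 in the same order, under the pseudocount of 5.13 in restricted hearts, and Aplnr 392 ± 117, 271 ± 115, 35.0 ± 6.81 and 509 ± 84.2.

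Against ad libitum hearts, 7 of 26 interferon responsive genes and 4 of 18 macrophage markers fell under restriction (adjusted p = 0.0852 and 0.314 for the lists by camera with an estimated correlation). A hypothesis was that both follow the amount of macrophages in a sample. With group means removed, the mean scores of the 2 lists, which share 0 genes, correlated over the 18 arrays (Pearson r = 0.801, permutation p = 2.1e-04; Spearman rho = 0.796, permutation p = 4e-04; 100000 resamples; 1 relation computed). Without wild type replicates 4 and 3, the 2 arrays farthest from the median, r was 0.824. A shared dependence on macrophage content would give such a correlation. A common signal acting on several cell types would give it as well, and so would array-to-array variation shared by many genes. No other pair of lists was compared, so the correlation does not decide between these.

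Genes next to Lep could differ between ob/ob and wild type mice because they were carried over with the mutation from the strain in which it arose. Averaged over the ob/ob groups, 95 genes were called against wild type (42 higher, 53 lower). Of the 100 nearest tested genes, 50 on each side of Lep, 5 had an unadjusted p under 0.01, against 686 of 13259 others (odds ratio 0.965, 95% interval 0.305 to 2.34, Fisher's exact test p = 1). The interval is too wide to tell a small excess from none.

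Whether the ob/ob genes lay on the wild type side with leptin over restriction was tested on other splits of the 10 treated arrays. Chance could not be excluded for the share of genes on 1 side (80%, highest other 92.5%, 34 of 100 splits as high). It could be excluded for the mean change (0.454, highest other 0.350, 1 of 100 splits as large, the real one). This may reflect chance, a larger return with leptin, or a move away from wild type under restriction, as hypotheses from the same data.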
